A study of Homo sapiens with 5 samples.

How the data were processed

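RNA from 5 cultures of TIME cells was measured on Clariom D arrays, 2 after co-culture with normal ovarian fibroblasts (NF replicates 1 and 2) and 3 after co-culture with cancer-associated ovarian fibroblasts (CAF replicates 1 to 3). Per the labels' protocols, 2 ng of total RNA was labelled per array with the assay for small inputs. The values used are the authors' processed table, 1 log2 signal per transcript cluster (a probe set for 1 transcript locus) and array, as deposited and used without further scaling. The log2 scale was read from the values, and the submitters' processing notes name MAS5 with no version or role. Background correction, scaling and genome build are not given in the sources used here, so the fold sizes hold on the authors' scale and no genome positions are given. The table has 138745 transcript clusters, 2995 of them controls, and array medians from 3.52 to 3.55. Its highest value is 19.93, reached on at least 1 array by 30 transcript clusters, so signals near it may be compressed. 1 tested gene reached it.

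Gene symbols came from the platform annotation, which can be old. 36176 transcript clusters have 1 symbol, 1119 have several and 98455 are unnamed here. Symbols were updated through the gene identifier in the RefSeq annotation of GRCh38.p14, which matched 25516 of the 36176. A gene was represented by its single-symbol transcript cluster with the highest mean over all 5 arrays, and 1576 of 33616 genes had more than 1. Genes were tested where that mean reached the median over all transcript clusters, 3.52, which left 21896. Genes named only on transcript clusters with several symbols were not analysed here.

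CAF and NF arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, Benjamini-Hochberg adjustment, threshold 0.05), a two-sided test with 3 residual degrees of freedom and 8.74 after moderation. The smallest called difference was 0.72 on the log2 scale and the median standard error 0.22. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists. Camera reads its statistic on the 3 residual degrees of freedom when the correlation is estimated. With a preset correlation it uses degrees of freedom set by the number of genes, so the p-values differ for this reason too. Some lists share genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The comparison, the filter, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named LPP, then the 12 genes with the largest log2 difference in each direction among those that passed with non-overlapping arrays, then in each list the 4 measured members with the smallest unadjusted p, leaving out clone-style, non-coding and pseudogene-style symbols. Not all list members it named are given in the text. A bound against the negative controls and an alternative restricted to genes above their 95th percentile were chosen after seeing the data.

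The procedure was tested on simulated data. In a simulated CAF minus NF comparison of 21896 genes, limma recovered 0 of 67 genes changed by 0.75 log2 units, 22 of 67 changed by 1.5 and 56 of 66 changed by 3, with 0 false calls among 78 calls. In this simulation most differences of 1.5 log2 units or less were missed. It changed only these few of 21896 genes, while 2011 were called in the data, so its adjusted threshold was stricter. The shares recovered therefore do not measure the power of the real comparison, where small differences may still be missed. Signal over background sets a second limit, since 8826 of the tested genes and 1598 of the called genes have a mean above the 95th percentile of the negative control probe sets. Alternatives covered normalization, filter, moderation, array weights, probe set choice, threshold, a replicate block and leaving out each array.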

Results

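Transcripts were measured in TIME cells, a telomerase-immortalised line of human microvascular endothelial cells, after co-culture with ovarian fibroblasts. In Boyden chambers, where a porous membrane parts the cell types, 10000 TIME cells shared medium for 48 h with 20000 primary fibroblasts. The fibroblasts were cancer-associated fibroblasts (CAFs) of the ovary for 3 arrays and normal ovarian fibroblasts (NFs) for 2 arrays. No TIME cells cultured alone were measured. A rise or fall below therefore means higher or lower with CAFs than with NFs, and which fibroblast type moved a gene cannot be told. The labels call the arrays biological replicates and do not say whether they came from different fibroblast donors. P-values therefore measure only the spread between these samples, part of which may be technical. If all arrays of a group shared a donor, fibroblast type could not be told apart from donor. RNA was hybridised to Clariom D arrays, and the number of arrays limits the precision. Array medians lay between 3.52 and 3.55 on the log2 scale. Over the 21896 genes tested, arrays of a group correlated at 0.991 to 0.992 and arrays of different groups at 0.977 to 0.978 (Pearson's r across genes, which are not independent replicates). Hybridisation controls differed by at most 0.18 log2 units over the 5 arrays, while the RNA control phe averaged 6.98 with NFs and 6.13 with CAFs, thr 7.68 and 7.28, dap 8.74 and 8.86, and lys 5.67 and 5.70.

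The comparison asks how the transcripts of endothelial cells differ between CAF and NF co-culture. Transcripts of the actin-binding protein gene TAGLN, the angiogenic factor VEGFA and the endothelial glycoprotein VWF were higher with CAFs, and those of the cyclin CCNB2, the histone gene H2BC14 and the sterol enzyme SQLE were lower. The largest rise was in TAGLN, which encodes the actin-binding protein transgelin. Its signal went from 5.43 ± 0.13 (SD, n = 2) with NFs to 12.77 ± 0.23 (SD, n = 3) with CAFs. LPP, which encodes the lipoma-preferred partner of focal adhesions and was the gene chosen for report before the data were examined, rose by 0.77 ± 0.20 on the log2 scale, a 1.71-fold difference. Its signal went from 9.38 ± 0.28 (SD, n = 2) with NFs to 10.15 ± 0.022 (SD, n = 3) with CAFs, and all 3 CAF arrays lay above both NF arrays. The adjusted p for LPP was 0.0493 (limma, Benjamini-Hochberg over 21896 genes). This call was lost when any of the 5 arrays was left out, with differences between 0.58 and 0.97 and adjusted p between 0.0791 and 0.228. It was also lost without a filter on low signals, without variance moderation, with array weights and over all transcript clusters of the table, where adjusted p ran from 0.0537 to 0.161.

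2011 of the 21896 genes passed an adjusted p of 0.05, of which 851 were higher and 1160 lower with CAFs. The larger share of lower genes depended on the setting, with 1010 higher and 993 lower after quantile normalization, and 418 and 396 without NF replicate 1. Of the 2011 genes 46 rose and 55 fell with a fitted difference of at least 3 log2 units. Every one of the 2011 genes had all 3 CAF arrays on one side of both NF arrays, which follows largely from the call and is no separate support. Among all tested genes, which are not independent, 37.9% were separated in this way, against 20% by chance. Left-out arrays lowered the count to 814 without NF replicate 1, 1078 without NF replicate 2 and 1332 without CAF replicate 1, and 608 genes passed whichever array was left out. The count was 114 without variance moderation and 1221 over all transcript clusters, named or not.

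The genes with the largest rises after TAGLN were the tetraspanin TSPAN18 (6.09 ± 0.24 on the log2 scale), the ubiquitin-like modifier UBD, the matrix protein TGFBI (5.15 ± 0.21), the integrin subunit ITGB3 and LRRC32 (4.80 ± 0.29), a cell surface receptor for latent TGF-beta. They were followed by the serine protease FAP (4.70 ± 0.27), the cholesterol exporter ABCA1, the collagen-modifying enzyme P3H2 (4.39 ± 0.23), the cyclin CCND2 (4.38 ± 0.19), PRND and the angiogenic growth factor VEGFA (4.35 ± 0.28). The largest falls were in the histone gene H2BC14 (-5.77 ± 0.24), the cystatin CST1, the chromatin protein HMGA1 (-4.90 ± 0.23), the oxidase AOX1 and the secreted glycoprotein STC1 (-4.07 ± 0.21). They continued with CST4, CCNB2 (-3.94 ± 0.20), PRC1 (-3.93 ± 0.28), TTK, FOXM1 (-3.83 ± 0.27), AURKB (-3.69 ± 0.24) and the tubulin TUBA4A (-3.67 ± 0.24). Adjusted p for these 24 genes ran from 2.81e-06 to 8.43e-05 (limma), and all 24 kept the call whichever array was left out. The ± values are standard errors of the fit, and genes given without one had a group at background level.

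Signals below 6.37, the 95th percentile of the array's 612 negative control probe sets, gave only a bound, counted against that percentile. Transcripts were at least 84.7-fold higher with CAFs for TAGLN, 6.59-fold for UBD, 4.41-fold for ABCA1 and 3.19-fold for PRND. For ITGB3 they were at least 15.99-fold higher. Transcripts were at least 17.0-fold lower for AOX1, 10.9-fold for TTK and 4.49-fold for CST1. CST4 was below that percentile in both groups, at 6.34 with NFs and 2.38 with CAFs. Among genes with a mean above it in both groups, fold differences were 68.0 for TSPAN18, 35.4 for TGFBI, 25.9 for FAP and 20.4 for VEGFA, and 54.7-fold lower for H2BC14 and 29.9-fold lower for HMGA1. The size for TSPAN18 is uncertain, as its signal on NF replicate 2, 6.25, lay below that percentile. The same holds for LRRC32 (6.36) and, given below, COL4A1 (6.18) and CCL2 (6.22) on that array. It also holds for AURKB on CAF replicate 1 (6.08), COL6A1 on NF replicate 1 (6.24) and IFIT3 on CAF replicate 3 (6.35). PCDHB14, given below, is uncertain likewise, at 6.44 ± 0.55 (SD, n = 2) with NFs. Histone genes and the cystatins CST1 and CST4 have near-identical copies, so which copy a probe set measured is uncertain.

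**Figure D1:**
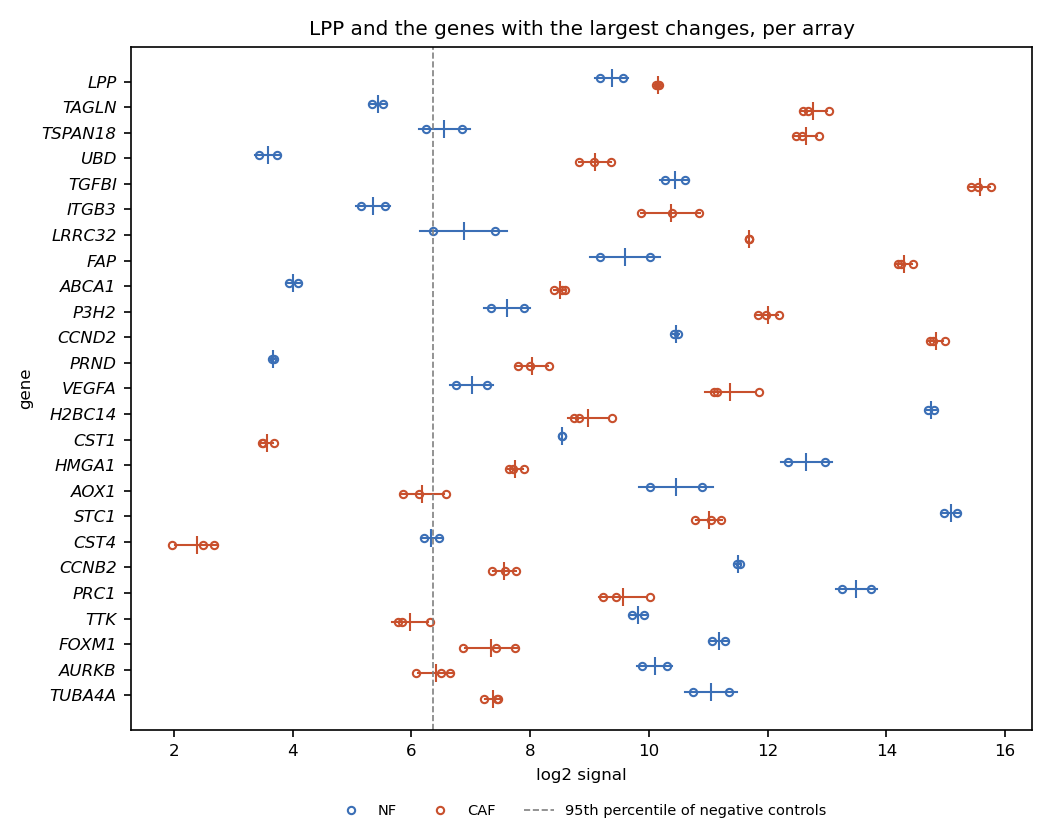
Log2 signal of LPP and of the 12 genes with the largest rise and the 12 with the largest fall, for each NF array (blue, n = 2) and CAF array (orange, n = 3), with the mean as a tick and the SD as a line. TAGLN averaged 5.43 with NFs and 12.77 with CAFs, and LPP 9.38 and 10.15.

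CCNB2, a B-type cyclin, fell by 3.94 ± 0.20, PLK1, a mitotic kinase, by 3.63 ± 0.19, and CCNA2, an S and G2 phase cyclin, by 3.05 ± 0.19, on the log2 scale. Of 40 measured cell cycle genes 36 fell and 4 did not pass, with 38 falling adjusted over the list alone and a median of -2.50 (camera adjusted p = 1.94e-40, and adjusted p = 0.0634 with an estimated correlation). All 12 measured histone genes fell, with 12 falling adjusted over the list alone and a median of -1.44. Their camera adjusted p was 1.47e-13, and adjusted p = 0.0634 with an estimated correlation. Among them H3C2 fell by 3.39 ± 0.19, the DNA damage histone H2AX by 2.88 ± 0.19 and H4C3 by 2.14 ± 0.19.

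P4HA1, a collagen prolyl hydroxylase, rose by 3.71 ± 0.19, the vasodilator peptide gene ADM by 3.33 ± 0.20 and VEGFA by 4.35 ± 0.28 on the log2 scale. Of 23 measured hypoxia genes 15 rose and 8 did not pass, with 19 rising adjusted over the list alone and a median of 1.18 (camera adjusted p = 2.47e-18, and adjusted p = 0.0634 with an estimated correlation). In the list of VEGF, Notch and tip cell genes, 14 of 28 rose, 1 fell and 13 did not pass, with 17 rising and 2 falling adjusted over the list alone. Its median was 0.69 (camera adjusted p = 4.62e-09, and adjusted p = 0.0687 with an estimated correlation). RGCC rose by 1.78 ± 0.21, the VEGF co-receptor NRP2 by 1.64 ± 0.20 and the pericyte-recruiting factor PDGFB by 1.67 ± 0.22. The gene that fell, picked after its values were seen, was the Notch target HEY1, which lay below the negative control percentile in both groups (5.38 with NFs and 3.95 with CAFs). The call of 1 gene depended on single arrays in limma: HEY1 without each of NF replicates 1 and 2 (adjusted p up to 0.124).

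TGFBI, a matrix protein induced by TGF-beta, rose by 5.15 ± 0.21, LRRC32 by 4.80 ± 0.29 and INHBA, the inhibin beta A subunit, by 3.12 ± 0.21 on the log2 scale. Of 26 measured TGF-beta and BMP genes 11 rose, 2 fell and 13 did not pass, with 12 rising and 2 falling adjusted over the list alone. The median was 0.57 (camera adjusted p = 2.21e-08, and adjusted p = 0.0634 with an estimated correlation). The fallers, picked after their values were seen, were the ligand BMP2 (-3.02 ± 0.23) and HEY1, below the negative control percentile in both groups, which lost its call without each NF array (adjusted p up to 0.124 in limma). BMP4 was below the negative control percentile in both groups, at 3.08 with NFs and 6.33 with CAFs (adjusted p = 8.25e-05). Of 23 measured basement membrane and protease genes 13 rose, 1 fell and 9 did not pass, with 15 rising and 2 falling adjusted over the list alone. Their median was 1.09 (camera adjusted p = 5.33e-09, and adjusted p = 0.0634 with an estimated correlation). NID1 rose by 2.78 ± 0.18, the collagen IV chains COL4A1 by 2.78 ± 0.26 and COL4A2 by 2.83 ± 0.24, and the urokinase gene PLAU by 2.04 ± 0.20. The faller, also picked after its values were seen, was the protease ADAMTS1, which lay below the negative control percentile in both groups (5.63 with NFs and 4.00 with CAFs).

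Among focal adhesion genes, the class to which LPP belongs, the integrin subunit ITGB3 was at least 15.99-fold higher with CAFs, ITGAV, its alpha partner, rose by 1.98 ± 0.20, the tropomyosin TPM1 rose by 2.49 ± 0.19, and the tensin TNS3 fell by 2.42 ± 0.22 on the log2 scale. Of 31 measured focal adhesion and actin genes 7 rose, 1 fell and 23 did not pass, with 9 rising and 2 falling adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.000182, and adjusted p = 0.273 with an estimated correlation). Of 14 measured targets of YAP and TEAD, transcription regulators that respond to mechanical tension, 7 rose, 1 fell and 6 did not pass, with 8 rising and 1 falling adjusted over the list alone. The median was 0.97 (camera adjusted p = 1.05e-05, and adjusted p = 0.0915 with an estimated correlation). AJUBA rose by 2.03 ± 0.20 and ANKRD1 by 1.76 ± 0.19, while the receptor tyrosine kinase gene AXL fell by 1.38 ± 0.21.

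VWF, the von Willebrand factor gene, rose by 4.34 ± 0.19 on the log2 scale, the sialomucin gene EMCN by 3.78 ± 0.28 and ENG, a TGF-beta co-receptor, by 1.89 ± 0.19. Of 24 measured endothelial identity genes 5 rose, 1 fell and 18 did not pass, with 8 rising and 1 falling adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.00156, and adjusted p = 0.273 with an estimated correlation). Of 10 measured lymphatic endothelial genes 5 rose and 5 did not pass, with 5 rising and 1 falling adjusted over the list alone and a median of 0.81 (camera adjusted p = 9.98e-05, and adjusted p = 0.0687 with an estimated correlation). SEMA3D rose by 1.86 ± 0.21, the hyaluronan receptor LYVE1 by 1.70 ± 0.21 and RELN by 1.40 ± 0.21. Of 21 measured junction and permeability genes 4 rose, 1 fell and 16 did not pass, with 7 rising and 1 falling adjusted over the list alone. The median was 0.37 (camera adjusted p = 0.000472, and adjusted p = 0.0915 with an estimated correlation). The phosphatase PTPRB rose by 3.19 ± 0.20 and beta-catenin, CTNNB1, by 1.51 ± 0.19, while the gap junction gene GJA1 fell by 0.95 ± 0.20. The VEGF receptor gene FLT4, the cadherin CDH5 and the adhesion receptor ICAM2, picked after their values were seen, were called too. CDH5 rose by 0.78 ± 0.20 and ICAM2 fell by 0.97 ± 0.20, while FLT4, with an NF mean below the negative control percentile, was at least 1.05-fold higher. Some of these calls were lost in limma when 1 array was left out: GJA1 without each of NF replicates 1 and 2 and CAF replicate 1 (adjusted p up to 0.132), FLT4 without NF replicate 1 (adjusted p = 0.0763), CDH5 without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.187) and ICAM2 without each of NF replicates 1 and 2 and CAF replicates 1 and 2 (adjusted p up to 0.132).

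SQLE, which makes squalene epoxide, fell by 2.43 ± 0.21 on the log2 scale, the sterol demethylase CYP51A1 by 2.48 ± 0.23 and HMGCS1, an early enzyme of the mevalonate pathway, by 2.80 ± 0.27. Of 17 measured cholesterol synthesis genes 13 fell, 1 rose and 3 did not pass, with 16 falling and 1 rising adjusted over the list alone. The median was -1.49 (camera adjusted p = 1.47e-13, and adjusted p = 0.0634 with an estimated correlation). The riser, picked after its values were seen, was STARD4 (0.85 ± 0.22), a sterol transport protein. The call of 1 gene depended on single arrays in limma: STARD4 without each of NF replicates 1 and 2 and CAF replicates 1 and 3 (adjusted p up to 0.211). The quinone reductase gene NQO1 fell by 3.51 ± 0.23, TXNRD1 by 2.14 ± 0.21, the cystine transporter SLC7A11 by 2.31 ± 0.23 and the metallothionein MT1E by 1.87 ± 0.24. Of 14 measured oxidative stress and metallothionein genes 8 fell and 6 did not pass, with 12 falling adjusted over the list alone and a median of -1.21 (camera adjusted p = 6.37e-11, and adjusted p = 0.0747 with an estimated correlation).

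The transcription factor gene FOSL1 fell by 3.33 ± 0.22 on the log2 scale, CCND1, the G1 cyclin, by 1.97 ± 0.19, and ETV5 by 1.55 ± 0.22. Of 23 measured ERK and immediate-early genes 7 fell and 16 did not pass, with 7 falling and 1 rising adjusted over the list alone. The median was -0.18 (camera adjusted p = 0.00718, and adjusted p = 0.411 with an estimated correlation). Without NF replicate 1 this list's adjusted p was 0.0715.

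The inositol trisphosphate receptor gene ITPR3 fell by 1.52 ± 0.24 and ITPR2 rose by 1.18 ± 0.25 on the log2 scale. NFATC2, whose NF mean was below the negative control percentile, was at least 1.55-fold higher with CAFs, and the kinase gene CAMK2D fell by 1.17 ± 0.23. Of 19 measured calcium and CREB signalling genes 3 rose, 3 fell and 13 did not pass, with 5 rising and 3 falling adjusted over the list alone, and the list was not called (median 0.10, camera adjusted p = 0.273). PPP3CA and PRKCA were picked after their values were seen. PPP3CA rose by 0.85 ± 0.20, and PRKCA lay below the negative control percentile in both groups (6.25 with NFs and 5.38 with CAFs). Some of these calls were lost in limma when 1 array was left out: ITPR3 without NF replicate 2 (adjusted p = 0.0510), ITPR2 without each of NF replicates 1 and 2 and CAF replicates 1 and 2 (adjusted p up to 0.158), NFATC2 without NF replicate 1 (adjusted p = 0.0571), CAMK2D without NF replicate 2 (adjusted p = 0.0942), PPP3CA without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.146) and PRKCA without each of NF replicate 1 and CAF replicates 1, 2, 3 (adjusted p up to 0.241).

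ICAM1, a leukocyte adhesion receptor, was at least 6.87-fold higher with CAFs, the chemokine gene CCL2 rose by 2.30 ± 0.24 and SOD2 by 1.72 ± 0.20 on the log2 scale. Of 22 measured NF-kB and leukocyte adhesion genes 6 rose, 1 fell and 15 did not pass, with 8 rising and 1 falling adjusted over the list alone. The median was 0.40 (camera adjusted p = 2.24e-05, and adjusted p = 0.0634 with an estimated correlation). The faller, picked after its values were seen, was the cytokine IL1A, with a CAF mean below the negative control percentile and at least 1.39-fold lower with CAFs. Of 16 measured p53 targets 5 rose and 11 did not pass, with 5 rising adjusted over the list alone and a median of 0.43 (camera adjusted p = 2.24e-05, and adjusted p = 0.0915 with an estimated correlation). TP53INP1 rose by 1.79 ± 0.19 and the growth factor gene GDF15, with an NF mean below the negative control percentile, was at least 2.38-fold higher. Interferon genes were not called as a list (median -0.0099, camera adjusted p = 0.809), with 3 of 24 falling, 21 not passing, and 1 rising and 5 falling adjusted over the list alone. The fallers were USP18 (-0.98 ± 0.22), IFIT3 (-1.27 ± 0.31) and ISG20 (-0.86 ± 0.21). The calls of USP18, IFIT3 and ISG20 were lost with quantile normalization too (adjusted p = 0.0562, 0.0668 and 0.0539 in limma). Some of these calls were lost in limma when 1 array was left out: IL1A without each of NF replicate 1 and CAF replicates 1 and 2 (adjusted p up to 0.193), GDF15 without NF replicate 2 (adjusted p = 0.0783), USP18 without each of NF replicates 1 and 2 and CAF replicates 1 and 2 (adjusted p up to 0.135), IFIT3 without each of NF replicate 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.182) and ISG20 without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.232).

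Of 24 measured ATF4 and unfolded protein genes 2 rose, 1 fell and 21 did not pass, with 5 rising and 2 falling adjusted over the list alone and a median of 0.21 (camera adjusted p = 0.0420, and adjusted p = 0.223 with an estimated correlation). The call was also lost with fry (adjusted p = 0.121), with the 75th percentile filter (adjusted p = 0.0526), with the replicate number as a block (adjusted p = 0.106) and without any 1 of NF replicate 2 and CAF replicates 1, 2 and 3 (camera adjusted p from 0.0609 to 0.114). SLC7A11 fell, as given above, DDIT4, below the negative control percentile with NFs, was at least 1.16-fold higher with CAFs, and the chaperone HSPA5 differed by 0.69 ± 0.19 without passing (adjusted p = 0.0546 in limma). DDIT4 lost its call without NF replicate 2 (adjusted p = 0.0541). In the heat shock list, 1 of 12 genes rose, 1 fell and 10 did not pass, with 1 rising and 4 falling adjusted over the list alone (median -0.38, camera adjusted p = 0.182, but 0.0305 without NF replicate 2). SERPINH1, the collagen chaperone, rose by 2.03 ± 0.20, and HSPE1 fell by 0.85 ± 0.21. The call of 1 gene depended on single arrays in limma: HSPE1 without each of NF replicates 1 and 2 and CAF replicates 1 and 2 (adjusted p up to 0.191).

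COL5A1, a fibrillar collagen, and FAP rose by 4.17 ± 0.20 and by 4.70 ± 0.27 on the log2 scale, and of the other measured fibroblast markers COL6A1 rose by 1.16 ± 0.24, COL1A2 by 0.94 ± 0.20 and FBN1, picked after its values were seen, by 1.29 ± 0.29. DCN, picked likewise, was called higher but lay below the negative control percentile in both groups (4.56 with NFs and 5.45 with CAFs). A second, dimmer COL1A2 probe set differed by -0.66. Of 17 measured fibroblast markers 6 rose and 11 did not pass, with 6 rising adjusted over the list alone and a median of 0.14 (camera adjusted p = 0.00135, and adjusted p = 0.0857 with an estimated correlation). In the pericyte and smooth muscle list, 2 of 9 rose, namely TAGLN and ACTG2, 7 did not pass, and 2 rose adjusted over the list alone. The list was not called (median 0.12, camera adjusted p = 0.103), though fry called it (adjusted p = 0.00327). Camera with the 75th percentile filter, which left 4 genes, called it too (adjusted p = 0.00367). The list mean of 0.79 came from TAGLN, with a fitted difference of 7.34. The list was not tested without TAGLN, so these calls do not show a rise of the list as a whole. ACTG2 was below the negative control percentile in both groups, at 4.31 and 5.08. Of 8 measured epithelial and ovarian carcinoma markers 1 rose, the keratin KRT7 (1.00 ± 0.19), 7 did not pass, and 1 rose adjusted over the list alone. Its median of -0.20 and its camera test, which pointed up, differed in sign (adjusted p = 0.809). A dimmer KRT7 probe set differed by -1.47. Of 9 measured leukocyte markers 1 fell, CD68 (5.58 with NFs and 4.43 with CAFs, both below the negative control percentile), 8 did not pass, and 1 fell adjusted over the list alone (median -0.057, camera adjusted p = 0.529). Some of these calls were lost in limma when 1 array was left out: COL6A1 without each of NF replicates 1 and 2 and CAF replicate 2 (adjusted p up to 0.138), COL1A2 without each of NF replicates 1 and 2 and CAF replicates 1 and 3 (adjusted p up to 0.111), FBN1 without each of NF replicates 1 and 2 (adjusted p up to 0.170), DCN without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.146), ACTG2 without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.223), KRT7 without each of NF replicates 1 and 2 (adjusted p up to 0.0850) and CD68 without each of NF replicate 1 and CAF replicates 1 and 2 (adjusted p up to 0.257).

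Ribosomal protein and respiratory chain genes were read as abundant transcripts outside the response lists. Of 26 measured ribosomal protein genes 2 fell, RPS15 by 1.01 ± 0.24 and RPL6 by 0.81 ± 0.21 on the log2 scale, 24 did not pass, and 2 fell adjusted over the list alone. The list's median was -0.16 (camera adjusted p = 0.0381, and adjusted p = 0.627 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.0888), with the 75th percentile filter (adjusted p = 0.0896), by fry (adjusted p = 0.128) and without NF replicate 1, CAF replicate 1 or CAF replicate 2 (adjusted p from 0.0602 to 0.219). Of 22 measured respiratory chain genes 22 did not pass in limma, 3 fell at an unadjusted p under 0.05, 1 passed with trended and robust moderation, and 0 passed adjusted over the list alone (median -0.26, camera adjusted p = 0.103, but 0.0305 without NF replicate 2 and 0.0412 without the filter). NDUFB9 differed by -0.62 ± 0.20 (adjusted p = 0.0966). Some of these calls were lost in limma when 1 array was left out: RPS15 without each of NF replicate 1 and CAF replicates 1, 2, 3 (adjusted p up to 0.199) and RPL6 without each of NF replicates 1 and 2 and CAF replicates 1, 2, 3 (adjusted p up to 0.234).

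Across the 26 lists, camera with a preset correlation of 0.01 called 19 at an adjusted p of 0.05, of which 13 pointed up and 6 down. With a correlation estimated from the 5 arrays, 0 lists passed by camera, 14 had an unadjusted p under 0.05, and fry, which tests whether a list's genes move one way on balance, called 18.

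**Figure D2:**
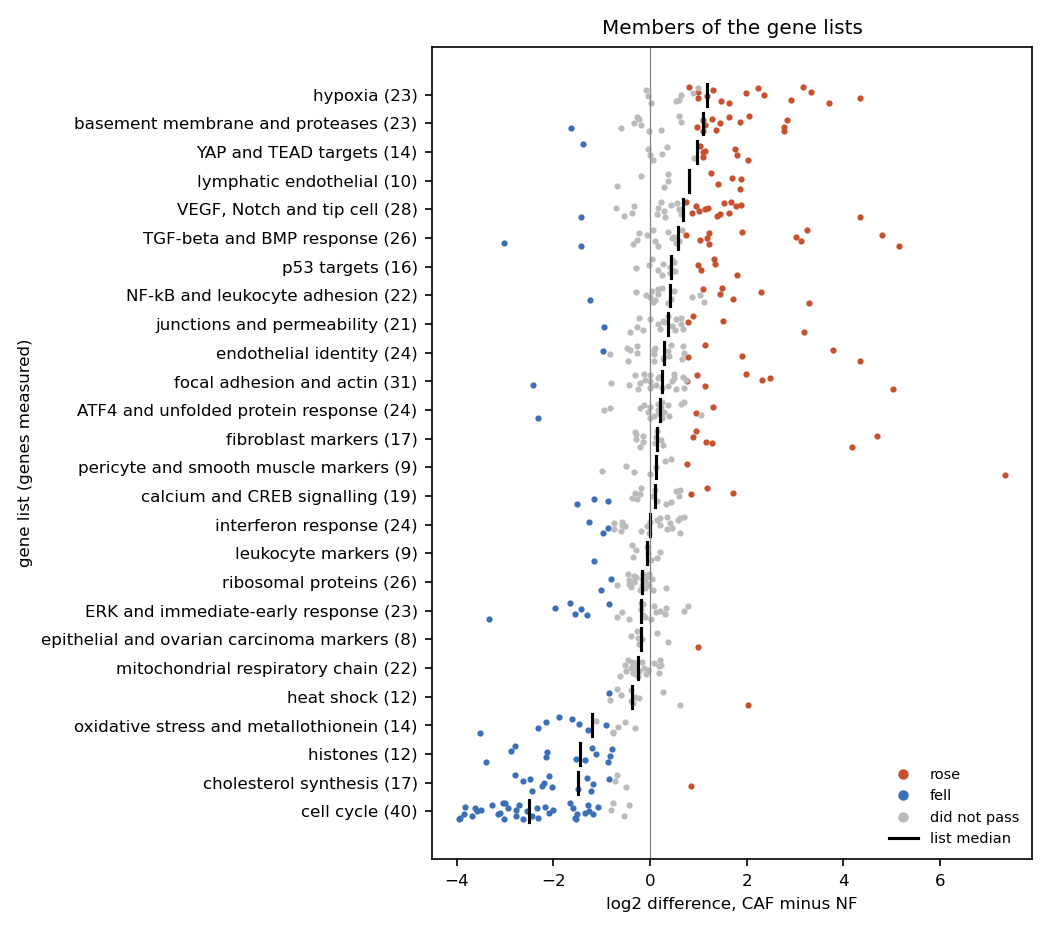
Log2 difference (CAF minus NF) of each measured member of the 26 gene lists, sorted by list median (black line), with points coloured by whether the gene rose, fell or did not pass at an adjusted p of 0.05. List medians run from -2.50 for cell cycle genes to 1.18 for hypoxia genes.

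**Figure D3:**
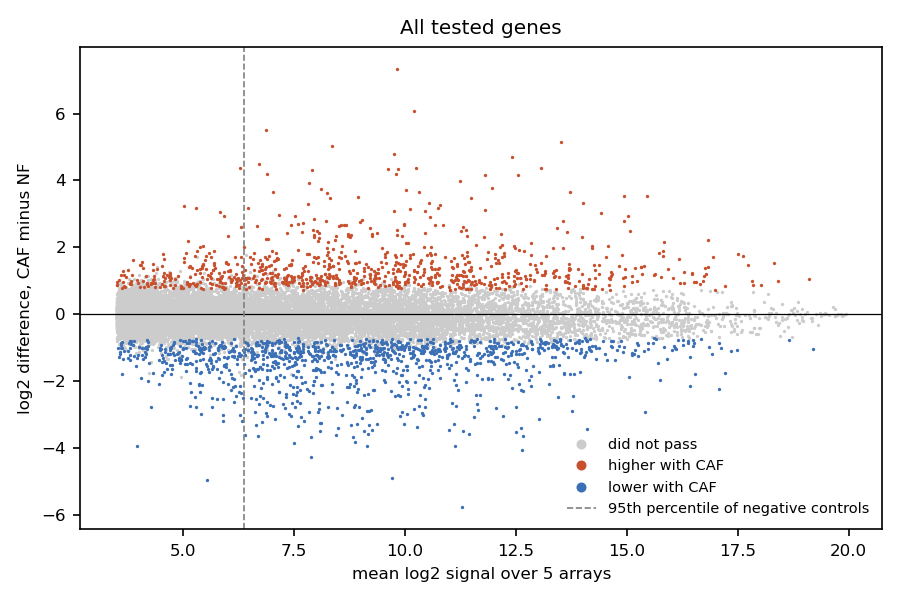
Log2 difference (CAF minus NF) against the mean log2 signal over the 5 arrays for 21896 tested genes, with 851 higher and 1160 lower with CAFs at an adjusted p of 0.05. The dashed line is the 95th percentile of the negative controls, 6.37.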

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

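Bootstrap intervals below resample genes with the 5 arrays held fixed, so they do not measure the spread between cultures. The 2 tests of fibroblast carry-over were chosen after their results had been seen. The other tests below were written before their own values were looked at, except that some small non-coding RNAs had been seen to fall. All were written after the patterns they bear on, and all are hypotheses found and tested on the same arrays.

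Transcript clusters without a gene name, which enter above only in the count over all transcript clusters, held a signal. Of 42431 unnamed transcript clusters fitted together with the named ones, 134 were higher and 107 lower with CAFs at an adjusted p of 0.05 (limma). TC2100007247.hg.1 and TC2100007248.hg.1 had fitted log2 differences of 4.72 (adjusted p = 0.000172) and 3.98 (adjusted p = 0.000719), but their NF means lay below the negative control percentile, so they were at least 6.95-fold and 2.94-fold higher. TC0100014276.hg.1 fell by 3.46, and TC2100007485.hg.1 fell by 2.73, on the log2 scale.

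The fall of cell cycle and histone genes was weighed against weaker labelling of RNA without a poly(A) tail and against fewer dividing cells. Small non-coding RNAs above the negative controls, which also lack a tail, had a median difference of -0.170 on the log2 scale (52 genes, 95% bootstrap interval -0.37 to 0.00380, 4 rose and 6 fell). Over 53 replication-dependent histone genes the median was -1.54, which argues against labelling as the whole cause of the histone fall. Weaker labelling of RNA without a tail would not cover cell cycle genes, whose transcripts carry one, and 36 of 40 of these fell (median -2.50). Some of the small non-coding RNAs had been seen to fall before this test. A quiescence list had a median of 0.287 with 3 of 12 genes rising and 1 falling, and missed the threshold with camera at the preset correlation (adjusted p = 0.164 over the 4 lists written for these tests), so it leaves open whether fewer cells were dividing with CAFs. A direct effect of the CAFs or of the NFs on division stays open and was not tested.

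The rise of FAP, COL5A1 and other mesenchymal genes was weighed against carry-over of fibroblast RNA and against TGF-beta signalling in the TIME cells. With CAFs, FAP stood at 14.29 and COL5A1 at 14.23, against 7.37 for COL1A1, 7.43 for COL1A2, 7.53 for COL6A1 and 10.34 for FBN1. The median gap was -6.75 on the log2 scale. Over these 4 markers the 95% bootstrap bounds, -6.86 and -3.89, are the lowest and highest gap. The 2 brightest probe sets of 1 gene lay a median of -10.26 apart over 81 genes at that level. Each probe set stands for its own transcript locus, so 2 of them need not measure the same RNA. Their distance therefore cannot gauge how far probe response varies between markers. No fibroblast RNA was measured, so the gap does not exclude carry-over. The same 4 markers differed between CAFs and NFs by a median of 1.05, with all but COL1A1 rising, so carry-over stays open for these rises too. The 95% bootstrap bounds, 0.11 and 1.29, are again the lowest and highest of the 4 values. The 11 other measured markers lay below the negative control percentile and were not used. Further TGF-beta targets had a median of -0.0127 with 1 of 12 rising (camera adjusted p = 0.653), which leaves TGF-beta signalling open too, as is another change in the TIME cells, which was not tested.

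The fall of sterol synthesis genes with the rise of ABCA1 and of ABCG1 (at least 9.68-fold higher, picked after its values were seen) was weighed against a shared fall of SREBP targets and against LXR activation, both biological, and no technical explanation was tested. Fatty acid synthesis genes, also SREBP targets, had a median of -0.782 with 2 of 6 falling, ACACA by 1.23 ± 0.19 and FADS2 by 1.08 ± 0.20 (camera adjusted p = 0.0176, fry adjusted p = 0.00759, and adjusted p = 0.246 with an estimated correlation). The list goes with lower SREBP activity as a hypothesis, but not all its members fell. FASN (-0.84) and SCD (-0.73) were lower without passing, ACLY differed by -0.16 and ACSS2 by 0.11. In the cholesterol synthesis list STARD4 rose, as given above. FADS2 lost its call without each NF array, and ACACA with the mean of its probe sets (adjusted p = 0.291 in limma). LXR targets other than ABCA1 and ABCG1 had a median of -0.265 over 5 genes, of which LPCAT3 rose by 1.25 ± 0.24, a call lost without NF replicate 2 (adjusted p = 0.0962), so LXR activation stays open.

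Of the 10 splits of the 5 arrays into 2 and 3, 1 gave as many genes as the real one, the real split itself, with 2011 genes against 0 for the highest other split by limma. The 9 other splits had 427 to 1635 genes at an unadjusted p under 0.05, and at most 0 called without moderation, where the real split had 4782 at that unadjusted p. With 10 splits the share cannot go under 0.1.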

How the results depend on the processing

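The restriction to genes above the negative controls, which gave 2356 genes, was chosen after the data were seen, and the other alternatives before. A planned change of pseudocount was not run, as the values are already log2. Over the settings run, the count of called genes kept within 1.5 times the main 2011 with quantile normalization, median centring, either other filter, trended moderation, array weights, the mean of a gene's probe sets and a threshold of 0.10. It fell to 114 without moderation (57 higher and 57 lower, with 3 residual degrees of freedom) and to 1221 over all transcript clusters (560 and 661, where more were tested). With 1 array left out the count was 814 to 1473, with 372 to 631 higher and 396 to 846 lower, from fewer samples, and a lone NF array was assumed to vary like the CAF arrays. All 2011 calls kept their sign with 1 array left out, which their non-overlapping arrays make certain, and 2 changed it with the mean of a gene's probe sets. LPP differed by 0.58 to 0.97 with 1 array left out, and by 0.77 without the filter, without moderation, with array weights and over all transcript clusters, each without passing, and it passed in the other settings without a block (adjusted p = 0.0175 to 0.0488). The lists called numbered 17 to 20 in other settings and 0 by camera with an estimated correlation (14 at an unadjusted p under 0.05, 18 by fry). For array weights the cause was not tested. The estimated correlation was negative for NF-kB and leukocyte adhesion (-0.027), lymphatic endothelial (-0.042) and fibroblast marker genes (-0.015), below the preset value. Their unadjusted camera p still rose, from 9.5e-06 to 0.0165, from 4.6e-05 to 0.0238 and from 0.00078 to 0.0363. This argues against a higher correlation among genes as the cause for these lists. The other called lists had positive estimates. For all lists, camera with an estimated correlation uses the 3 residual degrees of freedom, far fewer than with a preset one, which by itself raises p. How much of each loss came from this and how much from correlation was not tested.

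A fit with the replicate number as a block gave 1599 genes, 1453 of them shared, and 18 lists, with LPP at 0.78 (adjusted p = 0.116, with 1 residual degree of freedom). The difference of NF replicates 1 and 2 correlated with that of CAF replicates 1 and 2 at -0.017 across genes. No strong shared deviation of same-numbered samples was therefore seen. Only 2 numbers are shared and the labels state no pairing, so a weaker pairing cannot be excluded. Among the named genes other than LPP, 1961 of the values kept direction and side of the threshold, 270 lost the call, 22 gained it and 6 changed sign. With 1 array left out, FCER1G and PTPRC, both below the negative control percentile, and COL1A1 changed sign. FCER1G ran from -0.83 to 0.14, PTPRC from -0.78 to 0.056 and COL1A1 from -0.21 to 0.44, turning sign without NF replicate 1 and, for COL1A1, without CAF replicate 3. COL1A1 stood at -0.034 with the block, and KRT7 at -0.24 with the mean of its probe sets, where a dim probe set pulls the other way, and none of these values passed. The camera direction of 2 uncalled lists turned in some settings, and the cause was not tested. Epithelial and ovarian carcinoma markers turned with the mean of a gene's probe sets (adjusted p = 0.517), without shared genes (adjusted p = 0.920) and without NF replicate 2, with adjusted p from 0.433 to 0.892 over left-out arrays. Interferon genes turned with the 75th percentile filter (adjusted p = 0.526) and without NF replicate 2, with adjusted p from 0.318 to 0.892 over left-out arrays. Of the called genes, 580 had their lower group under the negative control percentile, where the size of a difference is least certain.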

Other observations

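Gene families grouped by symbol were tested after the calls had been seen, with a test that counts genes as independent, and the genes given with values were picked after those were seen. Among 217 families with at least 8 tested protein-coding genes, the clustered protocadherins PCDHB, cell surface cadherins best known from neurons, stood out among the risers. 10 of 15 rose with CAFs (hypergeometric adjusted p = 5.96e-08, median 1.23 on the log2 scale), among them PCDHB13 (1.57 ± 0.19) and PCDHB14 (1.92 ± 0.28). These genes are similar in sequence, and whether their probe sets tell them apart was not checked, so which members rose is uncertain. The semaphorin family, guidance ligands, had 5 of 13 rising (adjusted p = 0.0166), with SEMA3A by 3.09 ± 0.27, while SEMA7A, below the negative control percentile in both groups (3.48 with NFs and 5.27 with CAFs), lost its call without NF replicate 1 (adjusted p = 0.0762 in limma). The collagens had 7 of 25 rising (adjusted p = 0.0119), and the NPIPB family, whose copies are near-identical, 7 of 8 (adjusted p = 9.88e-07).

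Among the fallers the histone families H2BC and H2AC came first, both added by hand to the families formed from symbols. They had 15 of 16 and 10 of 12 genes lower with CAFs (hypergeometric adjusted p = 7.57e-14 and 5.96e-08). The kinesin motors had 13 of 32 lower (adjusted p = 1.68e-05) and a median of -0.23 on the log2 scale. KIF15 was at least 4.85-fold lower and at background level with CAFs. MCM genes had 6 of 10 lower (adjusted p = 0.00202) and CDC symbols 9 of 28 (adjusted p = 0.00723). Of the alpha-tubulins 5 of 8 fell (adjusted p = 0.00666), TUBA1C by 1.20 ± 0.19 on the log2 scale among them, a call lost with the mean of its probe sets (adjusted p = 0.135 in limma), and these tubulins are close copies. Of the anaphase-promoting complex genes 5 of 10 fell (adjusted p = 0.0168). No family named here changed the sign of its median under quantile normalization or median centring.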
